A study of Homo sapiens with 15 samples.

How the data were processed

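RNA was measured by sequencing in 4 human lung cell lines 72 h after transfection with control siRNA or with siRNA against RNF20. BEAS-2B is an immortalized line of normal bronchial epithelium, and A549, H1299 and H460 are non-small cell lung cancer lines. Each arm used 2 siRNAs, numbered 1 and 2 in the labels, and each siRNA has 1 library per line, so that the replicate number within a group is the siRNA number. Of the 15 libraries used, 7 are controls and 8 are knockdowns. A549 entered with control siRNA 2 alone, and an A549 library with control siRNA 1 was not analysed here. Nothing in the labels ties the libraries to separate cultures, so p-values measure only the spread between these samples, which holds the difference between 2 siRNA sequences and may otherwise be technical.

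The authors deposited 1 table of 18815 genes by 15 libraries, whose values are a score in the sense of a normalized read count rounded to whole numbers by the authors. Per the submitters' processing notes, TopHat2 2.0.8b and edgeR were used with builds hg19 and GRCh37. The counter, the annotation, the kind of normalization and the use of strand are not given in the sources used here. The values themselves show scaling: upper quartiles lay between 998 and 1048 in all libraries, and the whole numbers 8, 23 and 38 were missing from the A549 control library, as scaling followed by rounding leaves them. The raw depth of each library is therefore unknown, and no counting interval can be given. Normalized totals ran from 16890078 to 26512117, and the 10 most abundant genes took 3.57% to 9.02% of a library. Median-of-ratios factors computed on the deposited values lay between 0.971 and 1.02 and TMM factors between 0.983 and 1.02, so no further scaling was applied. A count model needs unnormalized counts and was not used. Because strand use is unknown, reads of overlapping or antisense genes cannot be told apart, and genes with near-identical copies are treated as uncertain. No genome of the submitters' build was used, so positions are not given.

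A total of 13 repeated gene rows were removed, which left 18802, of which 1050 were 0 in every library. In 28 symbols, 24 of them among the tested genes, a date stood in place of the name, and none of these is named. Genes with at least 10 normalized counts in at least 2 libraries were tested, 14844 in all. Values were taken as log2(value + 1), and every fold change is on that scale, which understates the change of genes with low values. All 15 libraries entered 1 limma model (limma 3.58.1, R 4.3.3) with a mean for each of the 8 groups and moderated variances with a mean-variance trend (7 residual and 4.29 prior degrees of freedom). A549, with 1 control library, leans on the spread of the other groups. The 7 contrasts were knockdown minus control in each line, the mean over 4 lines, the mean over the 3 cancer lines, and the cancer mean minus BEAS-2B. Tests were two-sided with Benjamini-Hochberg adjustment over all tested genes within a contrast and a threshold of 0.05. An SE given with a change is the moderated one of the contrast.

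The groups, contrasts, tests, gene lists and rule for naming genes were fixed before the data were examined. The 24 gene lists were H2B ubiquitination machinery, replication-dependent histones, p53 targets, G1/S genes, G2/M genes, homologous recombination and Fanconi genes, mesenchymal genes, epithelial genes, matrix remodelling and adhesion, NF-kB and cytokine genes, interferon-stimulated genes, cholesterol synthesis, fatty acid synthesis, hypoxia and glycolysis, unfolded protein and amino acid response, TGF-beta and YAP targets, NRF2 targets, apoptosis regulators, ribosome biogenesis, immediate early genes, HOX genes, alveolar and airway differentiation, cytosolic ribosomal proteins, and mitochondrial transcripts. The mitochondrial list had 0 of its 13 genes in the table and could not be tested, which left 23 lists. RNF20 is in no list. Lists with at least 5 tested genes were tested with camera at a preset inter-gene correlation of 0.01, with adjustment over the lists, and again with the correlation estimated from the residuals and with fry. There were also 5 lists of markers of other cell types (basal epithelial, neuroendocrine, immune, endothelial and fibroblast).

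RNF20 and its partner RNF40 are always named. For the mean over 4 lines the named genes are the 10 largest rises and 10 largest falls among called genes with the same direction in every line, where genes in the lowest quartile of mean level are passed over. For each line and for the difference between cancer lines and BEAS-2B they are the 4 largest rises and falls in the same range of level, for a line with both knockdown libraries on the same side of its controls. From each list up to 4 called members with the smallest adjusted p are named, and uncharacterized, read-through and antisense genes are passed over. Some genes that this rule gives are not reported here. A gene named outside this rule is marked as chosen after its values were seen.

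Each step was tested on simulated data drawn at the real means of 14844 genes. At 2-fold the share of changed genes recovered was 88.1% for the mean over 4 lines, 65.7% for BEAS-2B, 64.2% for A549, 71.6% for H1299, 70.1% for H460, 86.6% for the mean over the cancer lines and 53.7% for the difference. At 1.5-fold it was 61.2% for the mean over 4 lines and between 23.9% and 32.8% for a single line. Between 0.0555% and 0.125% of unchanged genes were called. A list shifted by 0.5 on the log2 scale was called, and 0 of the unshifted lists were called by camera. The simulated genes were independent and had the same spread in every group. These rates therefore do not cover correlated lists, such as cholesterol synthesis with an estimated correlation of 0.843, or groups of unequal spread.

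Alternatives fixed before the data were examined were another pseudocount (0.25), no filter, a stricter filter (50), 2 other scalings, the replicate number as a block, siRNA identity as a random block, each RNF20 siRNA alone, each line fitted alone, and each library left out in turn. Leaving out the A549 control library takes the whole of A549 out of every contrast. The mean over 4 lines is then that of BEAS-2B, H1299 and H460. Alternatives chosen after seeing the data were the whole of H460 or of BEAS-2B left out, the H1299 share subtracted from the H460 control libraries, length and GC trends removed, and crossed numbers in BEAS-2B. Transcript length and GC content were those of the longest protein-coding transcript of each gene in GENCODE, used for these properties alone, and had a value for 98.5% of the tested genes. Scripts ran in R 4.3.3 and Python 3.11.15, and figures were drawn with matplotlib 3.10.9.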

Results

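RNA sequencing measured gene expression in BEAS-2B, A549, H1299 and H460 cells 72 h after transfection with control siRNA or siRNA against RNF20, the E3 ubiquitin ligase that with RNF40 attaches ubiquitin to histone H2B. Each group held 2 libraries, 1 for each of 2 siRNAs, except the A549 control group with 1. Normalized totals ran from 16890078 in a BEAS-2B library to 26512117 in an H460 library, and the raw depth behind them is unknown. All levels are normalized read counts, given as mean ± SD (n = 2) unless a single library is named, and all adjusted p-values are from limma. The series set normal beside malignant lung epithelial cells and asked which genes changed when RNF20 was lowered in each.

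RNF20 itself was lower in all 8 knockdown libraries. In BEAS-2B it went from 1598 ± 61.5 to 227 ± 56.6, which left 14.2% of the control level, with 11.7% left by siRNA 1 and 16.7% by siRNA 2. In A549 it went from 1636 in the 1 control library to 155 ± 4.24 (9.47% left). In H1299 it went from 1889 ± 140 to 90.5 ± 12 (4.79% left), and in H460 from 1937 ± 2.83 to 177.5 ± 51.6 (9.16% left). Averaged over the 4 lines RNF20 fell by 3.52 on the log2 scale (SE 0.104, adjusted p = 1.38e-08). The highest knockdown library, BEAS-2B with siRNA 2, stood at 267 and the lowest control library at 1554. RNF40, which forms the ligase complex with RNF20, had a mean log2 change of 0.11 (SE 0.0495, adjusted p = 0.125) and did not pass the test. After knockdown it stood at 118%, 101%, 114% and 100% of its control level in BEAS-2B, A549, H1299 and H460. In BEAS-2B the 2 siRNAs differed, with 131% for siRNA 1 and 105% for siRNA 2.

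**Figure D1:**
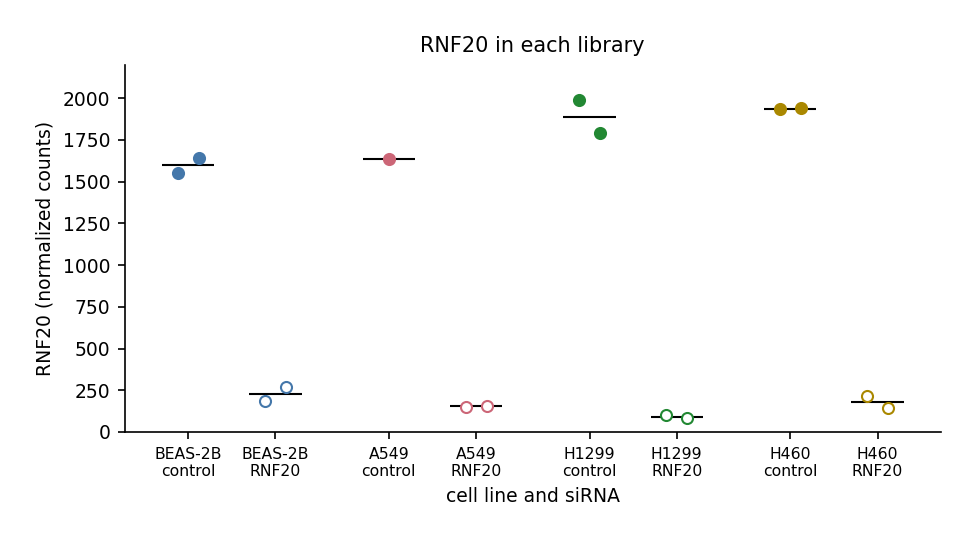
RNF20 level in each library (normalized read counts), with points for single libraries and bars for group means, by cell line and siRNA arm. All 8 knockdown libraries lie between 82 and 267, and all 7 control libraries lie between 1554 and 1988.

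Among genes that moved in the same direction in every line and stood above the lowest quartile of level, the largest mean rise was that of E2F2, a transcription factor that drives entry into DNA replication. It rose 2.51-fold (log2 change 1.33, SE 0.0849, adjusted p = 3.53e-06), from 29 to 138.5 ± 16.3 in A549, from 260.5 ± 36.1 to 597.5 ± 6.36 in H1299 and from 53.5 ± 6.36 to 183.5 ± 30.4 in H460. BEAS-2B had 871 ± 41.0 and 968 ± 62.2. PTPMT1, a mitochondrial phosphatase of cardiolipin synthesis, rose 2.01-fold with the smallest p of the rises in this paragraph (adjusted p = 1.27e-07), with log2 changes of 1.14 in A549, 1.29 in H1299, 1.56 in H460 and 0.05 in BEAS-2B. The epithelial transcription factor EHF rose 2.02-fold (adjusted p = 0.00177), SPP1, which encodes osteopontin, 1.99-fold (adjusted p = 0.000615), the kinesin heavy chain KIF5C 1.98-fold (adjusted p = 0.000106) and the vascular growth factor ANGPT1 1.96-fold (adjusted p = 0.0011). Lines near the floor carried part of these means: SPP1 had log2 changes of 2.20 in BEAS-2B, where both controls were listed at 0, and of 0.60, 0.88 and 0.31 in A549, H1299 and H460. EHF had 1.95 in H1299, from 0.5 to 4.5. SYT11, a member of the synaptotagmin family, rose 2.3-fold (adjusted p = 0.00287) and FRY 2.00-fold (adjusted p = 0.00025). ALDH3A1, an aldehyde dehydrogenase, rose 2.12-fold with an SE of 0.325 (adjusted p = 0.0294). Its call was lost in 10 of the 15 fits that each left out 1 library, with an adjusted p of up to 0.188.

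Among the falls shared in direction by all 4 lines, the interleukin 6 receptor gene IL6R fell 2.88-fold on average (log2 change −1.53, SE 0.0735, adjusted p = 3.53e-07). Its level went from 1699 to 354.5 ± 9.19 in A549, from 324 ± 9.90 to 112 ± 26.9 in H1299 and from 5938 ± 397 to 1356 ± 21.9 in H460. It stood at 652 ± 31.1 and 578.5 ± 60.1 in BEAS-2B. GXYLT1, a xylosyltransferase that modifies Notch receptors, fell 2.48-fold (log2 change −1.31, SE 0.0408, adjusted p = 1.38e-08), in H460 from 4674 ± 104 to 1030 ± 77.1. The G protein subunit gene GNG10 fell 2.3-fold (adjusted p = 2.86e-07), the ceramidase ACER2 2.90-fold (adjusted p = 0.000176), the apolipoprotein APOC1 3.11-fold (adjusted p = 0.000739) and the cytokine IL32 2.34-fold (adjusted p = 0.00126). The acute-phase genes SAA1 and SAA2 fell 2.65-fold and 2.71-fold (adjusted p = 0.00795 and 0.00566), but as near-identical copies they may share reads. Neither passed in the mean left without the A549 control library, that of BEAS-2B, H1299 and H460 (adjusted p = 0.0533 and 0.0530). There SAA1 had a log2 change of −1.03. HMGA2, a chromatin protein, fell on average (log2 change −1.66, SE 0.162, adjusted p = 4.48e-05) and went from 1384 to 417.5 ± 17.7 in A549. In H460 it went from 275.5 to 15.5, a loss of 260, where the H1299 share measured in the H460 control libraries (described with H460) would account for 330, more than the whole control level. Without H460 the HMGA2 log2 change on average over 4 lines, here the other 3, was −0.90 (adjusted p = 0.000505).

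**Figure D2:**
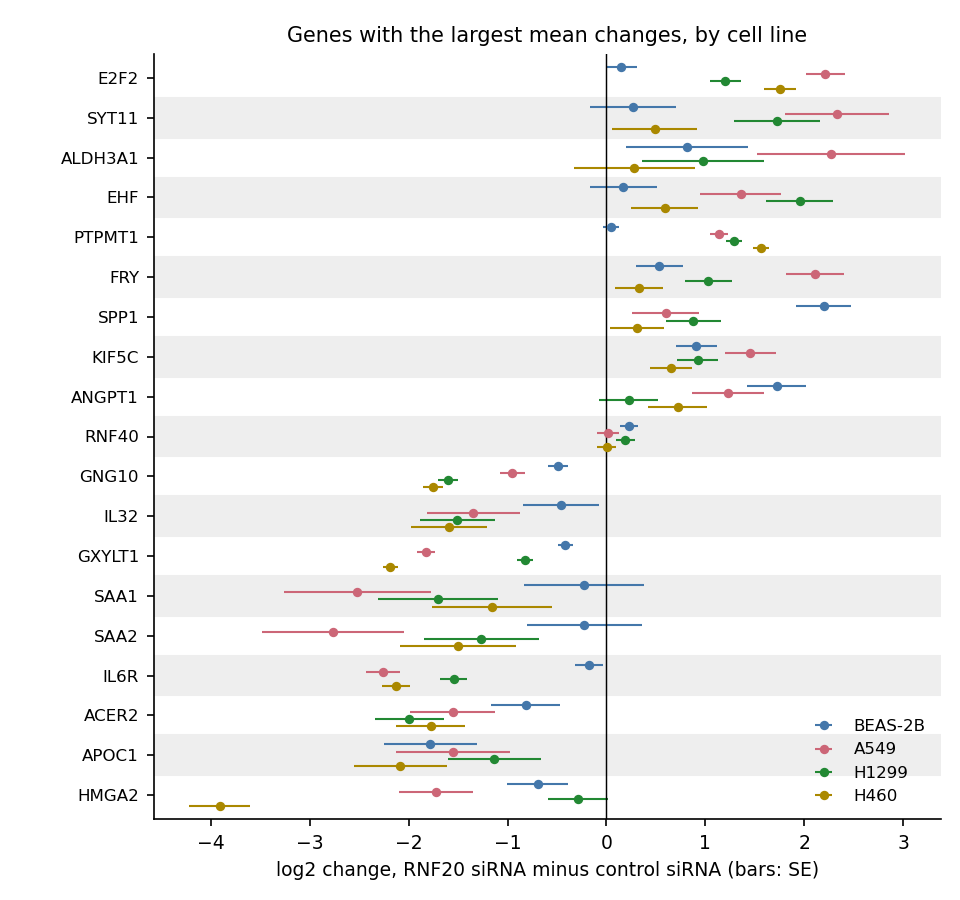
Log2 change with RNF20 siRNA against control siRNA (log2 of the normalized read count plus 1) of named genes in each cell line, with points for the estimate and bars for its SE. PTPMT1 lies near 0 in BEAS-2B (0.05) and above 1 in A549, H1299 and H460, and IL6R lies at −0.18 in BEAS-2B and between −2.26 and −1.54 in the other lines.

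Over the 4 lines, 4005 of 14844 tested genes changed on average (limma, adjusted p under 0.05), 1935 higher and 2070 lower, and 132 of these changed by 2-fold or more (72 higher, 60 lower). Among the 4005 genes, 2136 had the same direction in every line, 1047 higher and 1089 lower. The number of genes changed on average over 4 lines was 1712 without H460 and 6470 without BEAS-2B.

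Cell cycle genes rose in the mean over 4 lines, and not in BEAS-2B, where limma called 0 of the 24 G1/S and 0 of the 24 G2/M genes by either adjustment (medians −0.01 and −0.09, camera adjusted p = 0.906 and 0.0756). Of 24 G1/S genes, which carry cells into DNA replication, 17 rose and 0 fell over all genes tested, and 18 rose and 1 fell adjusted over the list alone (median log2 change 0.35, camera adjusted p = 1.44e-09, adjusted p = 0.182 with an estimated correlation). Besides E2F2, the replicative helicase genes MCM5 and MCM6 each rose by 0.43 on the log2 scale (adjusted p = 2.67e-05 and 7.7e-05) and CDC45 by 0.57 (SE 0.0585, adjusted p = 6.45e-05). Of 24 G2/M genes, which drive mitosis, 17 rose and 1 fell, and 18 rose and 1 fell adjusted over the list alone (median 0.27, camera adjusted p = 1.02e-07, adjusted p = 0.191 with an estimated correlation). The mitotic activator CDC20 rose 1.43-fold (adjusted p = 1.99e-05), the survivin gene BIRC5 1.39-fold (adjusted p = 3.13e-05), the spindle checkpoint kinase BUB1 1.30-fold (adjusted p = 0.000102) and NUSAP1 1.21-fold (adjusted p = 0.000454). Of 19 homologous recombination and Fanconi genes, which repair DNA breaks and crosslinks, 10 rose and 0 fell, and 11 rose and 1 fell adjusted over the list alone (median 0.18, camera adjusted p = 0.000708, adjusted p = 0.191 with an estimated correlation). They included EXO1 (log2 change 0.50, adjusted p = 0.00125), XRCC2 (0.47, adjusted p = 0.00224), FANCD2 (0.35, adjusted p = 0.00155) and BLM (0.29, adjusted p = 0.00506). In H1299 the G2/M list was not called (median 0.06, 3 higher and 1 lower, adjusted p = 0.200). There the homologous recombination list had 0 members higher and 2 lower (median −0.11, adjusted p = 0.745), and in BEAS-2B its median was 0.04 (adjusted p = 0.426). Without H460, XRCC2, FANCD2, BLM and NUSAP1 no longer passed (adjusted p = 0.0815, 0.0887, 0.242 and 0.0578).

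Targets of p53 fell as a list. Of 23 tested members, 14 fell and 0 rose, and 20 fell and 0 rose adjusted over the list alone (median log2 change −0.41, camera adjusted p = 6.20e-09, adjusted p = 0.191 with an estimated correlation). The death receptor gene TNFRSF10B fell 1.51-fold (SE 0.0380 on the log2 scale, adjusted p = 3.53e-06), TP53INP1 1.53-fold (adjusted p = 8.04e-06), and the stress-response genes SESN2 and SESN1 1.49-fold and 1.75-fold (adjusted p = 1.55e-05 and 3.72e-05). Among 18 replication-dependent histone genes, 6 fell and 0 rose by both adjustments, over all genes and adjusted over the list alone (median −0.39, camera adjusted p = 0.00177, adjusted p = 0.352 with an estimated correlation). The linker histone gene HIST1H1C fell 1.78-fold (SE 0.0902, adjusted p = 9.03e-05). HIST1H2BD, HIST1H2BC and HIST1H3H (log2 changes −0.42, −0.58 and −0.88) were at fewer than 10 in BEAS-2B and did not pass without H460. Histone genes have near-identical copies, and reads could be split between them. Of 19 apoptosis regulators, 2 rose and 7 fell, and 2 rose and 9 fell adjusted over the list alone (median −0.16, camera adjusted p = 0.0231, adjusted p = 0.182 with an estimated correlation). The 3 named members that fell promote cell death: BMF (log2 change −1.14, SE 0.111, adjusted p = 4.48e-05), APAF1 (−0.58, adjusted p = 0.000319) and BCL2L11 (−0.36, adjusted p = 0.00132). BMF did not fall in BEAS-2B. Of 19 NF-kB and cytokine genes, 1 rose and 7 fell by both adjustments, over all genes and adjusted over the list alone (median −0.19, camera adjusted p = 0.0263, adjusted p = 0.383 with an estimated correlation). The adhesion gene ICAM1 fell 1.78-fold (adjusted p = 4.13e-05), the cytokine LIF 1.52-fold (adjusted p = 1.21e-05), NFKB2 1.48-fold (adjusted p = 0.000124) and TNFAIP3 1.28-fold (adjusted p = 0.000669). In BEAS-2B the NF-kB list had a median of 0.10 and was not called (camera adjusted p = 0.801). The inhibitor of cell death BCL2L1 (0.21) and its opponent BID (0.27), and in the NF-kB list TNFAIP2 (0.45), rose and were chosen after their values were seen. The apoptosis call was lost without BEAS-2B (adjusted p = 0.0737), and the NF-kB call with siRNA 1 alone (adjusted p = 0.262).

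Of 18 targets of NRF2, the regulator of the oxidative stress response, 9 rose and 1 fell, and 10 rose and 1 fell adjusted over the list alone (median log2 change 0.27, camera adjusted p = 0.000328, adjusted p = 0.182 with an estimated correlation). The quinone reductase NQO1 rose 1.45-fold (SE 0.0698, adjusted p = 0.000292), and the near-identical aldo-keto reductases AKR1C1 and AKR1C2, which may share reads, 1.36-fold and 1.43-fold (adjusted p = 0.000148 and 8.91e-05). The heme oxygenase HMOX1 rose 1.70-fold (adjusted p = 0.000309), with a log2 change of 2.13 in A549. Without the A549 control library, and so over BEAS-2B, H1299 and H460 alone, its mean log2 change was 0.31 (adjusted p = 0.0610). Of 19 ribosome biogenesis genes, 11 rose and 1 fell, and 12 rose and 1 fell adjusted over the list alone (median 0.23, camera adjusted p = 2.09e-05, adjusted p = 0.196 with an estimated correlation). RRP9 rose 1.42-fold, the nucleolin gene NCL 1.36-fold, PES1 1.34-fold and MYC 1.28-fold (adjusted p = 0.000139, 0.000129, 8.25e-05 and 0.000445). Of 21 epithelial genes, 4 rose and 0 fell by both adjustments, over all genes and adjusted over the list alone (median 0.25, camera adjusted p = 0.0233, adjusted p = 0.383 with an estimated correlation). They were the tight junction gene CLDN1 (log2 change 0.44, adjusted p = 0.000478), the keratins KRT7 (0.38, adjusted p = 0.0168) and KRT18 (0.22, adjusted p = 0.0196), and the splicing factor ESRP1 (0.82, adjusted p = 0.0363). With the replicate number as a block KRT7, KRT18 and ESRP1 lost their calls in limma (adjusted p = 0.127, 0.0809 and 0.0624). The calls of ESRP1 and KRT18 were lost in 11 and 3 of the 15 fits that each left out 1 library. Members that moved against their list, chosen after their values were seen, were HMMR (−0.23, G2/M), ABCC2 (−0.49, NRF2) and UBTF (−0.17, ribosome biogenesis). With an estimated correlation, 0 of the 23 lists were called by camera, 5 had an unadjusted p under 0.05, and fry called 14, among them all 10 that camera called with the preset correlation. The epithelial and NF-kB calls were lost without the A549 control library and without BEAS-2B RNF20 siRNA 2, the epithelial call with siRNA 1 alone (adjusted p = 0.0702), and the NF-kB call also without H460 control siRNA 2, with adjusted p of up to 0.0564 and 0.163 in the fits without 1 library.

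**Figure D3:**
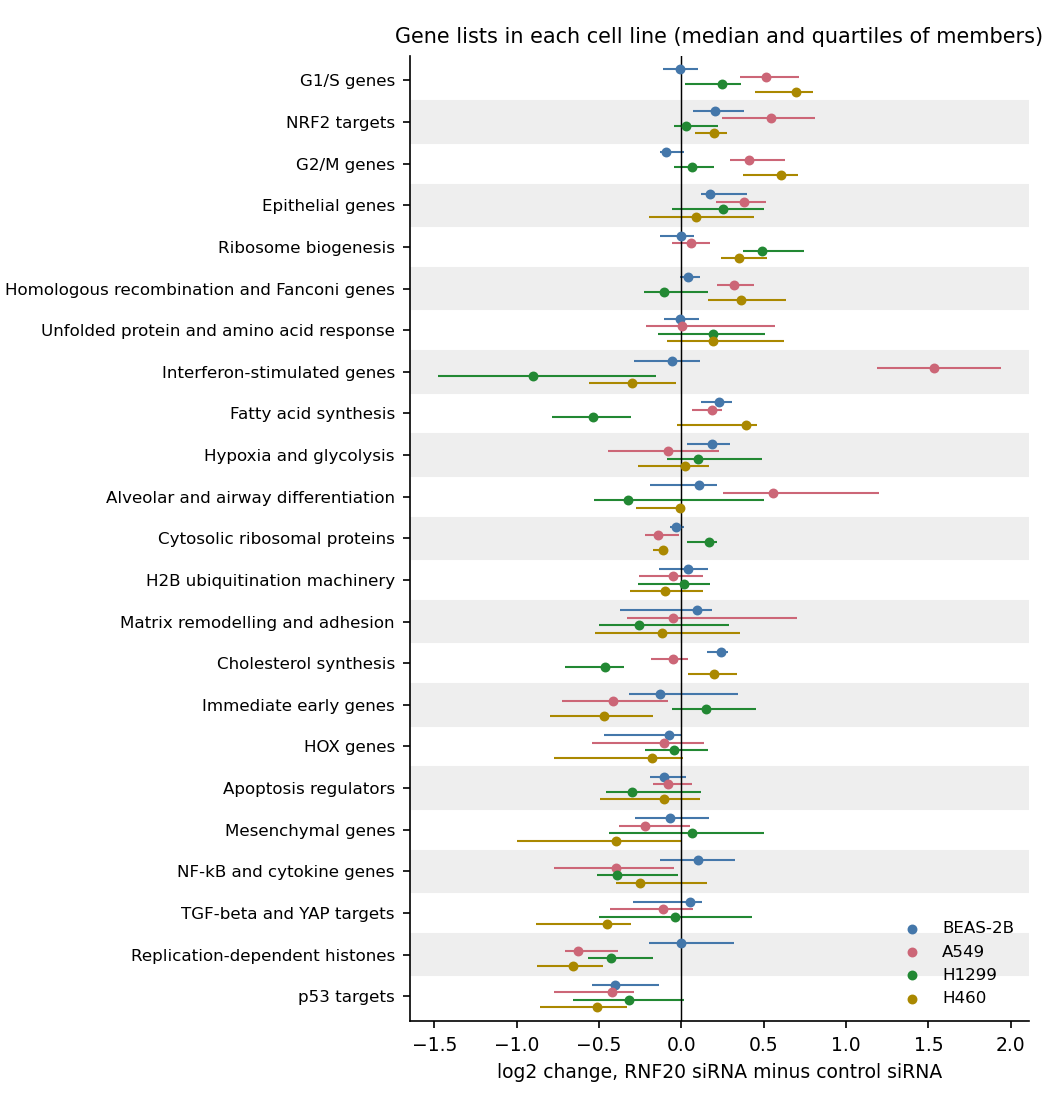
Log2 change with RNF20 siRNA against control siRNA of the members of 23 gene lists in each cell line, with points for the median and bars for the quartiles of the members. The median of the interferon-stimulated genes lies at 1.53 in A549 and at −0.90 in H1299, and that of the p53 targets lies below 0 in all 4 lines.

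The other 13 tested lists were not called in the mean over 4 lines. In the H2B ubiquitination machinery 4 genes rose and 4 fell (5 and 5 adjusted over the list alone, median −0.04, adjusted p = 0.638), with SUPT16H, a subunit of the histone chaperone FACT, at 0.35 and ATXN7L3, a subunit of an H2B deubiquitinase, at −0.33 (adjusted p = 0.000378 and 0.000515). Of the mesenchymal genes 2 rose and 5 fell by both adjustments, over all genes and over the list alone (median −0.17, adjusted p = 0.109), among them SPARC (−0.95, adjusted p = 0.000908), ACTA2, ITGA5 and COL1A1, of which the last 3 lost their calls without H460 (adjusted p = 0.0743, 0.0518 and 0.111). Of the TGF-beta and YAP targets 1 rose and 7 fell by both adjustments (median −0.23, adjusted p = 0.0582), and the AXL log2 change on average over 4 lines, that of a receptor kinase, was −0.81 (adjusted p = 0.000316) and, with the H1299 share subtracted, −0.68 (adjusted p = 0.00236), but −0.43 without H460 (adjusted p = 0.103). Of the HOX genes 0 rose and 5 fell by both adjustments (median −0.15, adjusted p = 0.0635), and the HOXB4 log2 change on average over 4 lines was −1.40 and, with the H1299 share subtracted, −0.82 (adjusted p = 0.00597). The HOXB3 log2 change on average over 4 lines was −0.42 and, with that share subtracted, −0.35 (adjusted p = 0.0105). In H460 16.8 of its loss of 32.5 would come from the share. The unfolded protein and amino acid response list had 8 rises and 2 falls (9 and 4 adjusted over the list alone, median 0.17, adjusted p = 0.0635), with the asparagine synthetase ASNS at 0.64 and the serine synthesis gene PHGDH at 0.48 (adjusted p = 0.000807 and 7.36e-05) and the chaperone DNAJB9 at −0.50 (adjusted p = 4.53e-05). The immediate early genes had 1 rise and 6 falls by both adjustments (median −0.11, adjusted p = 0.0658), with FOSL1 at −0.40 (adjusted p = 6.2e-05). Of the interferon-stimulated genes 8 rose and 6 fell by both adjustments (median 0.11, adjusted p = 0.363), and the lines moved apart as described for A549 and H1299. Without the A549 control library A549 left the mean altogether. Over BEAS-2B, H1299 and H460 the mean of this list was −0.37 and the list was called lower (camera adjusted p = 5.82e-06). In these lines ISG15 and DDX58 had mean changes of −0.28 and −0.06, against 0.40 and 0.36 with A549 included. Lists that were not called with all libraries were called in some fits that left out 1 library: HOX genes without BEAS-2B control siRNA 1, BEAS-2B RNF20 siRNA 1, the A549 control or either H460 control; TGF-beta and YAP targets without BEAS-2B control siRNA 2 or RNF20 siRNA 2; and mesenchymal genes without BEAS-2B RNF20 siRNA 2. Immediate early genes were called without BEAS-2B RNF20 siRNA 1 or H460 control siRNA 1, and the unfolded protein list without BEAS-2B RNF20 siRNA 1 or the A549 control, with adjusted p of at most 0.0475 in these fits.

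Hypoxia and glycolysis had 5 rises and 2 falls (5 and 3 adjusted over the list alone, median 0.07, adjusted p = 0.30), with the glucose transporter SLC2A1 at 0.45 (adjusted p = 0.000237). In cholesterol synthesis 2 genes, SC5DL and INSIG1, fell over all genes and 1 fell adjusted over the list alone (median −0.05, adjusted p = 0.505). INSIG1 lost its call in 9 of the 15 fits that each left out 1 library, and without BEAS-2B RNF20 siRNA 2 the list was called lower (adjusted p = 0.00204), while without RNF20 siRNA 1 its mean was 0.06. In fatty acid synthesis FADS1, ELOVL5 and ELOVL6 fell, and 1 rose and 3 fell adjusted over the list alone (adjusted p = 0.927). The median of that list was 0.11 and its mean 0.02, although the test leaned down. Without BEAS-2B RNF20 siRNA 2 the means of the fatty acid, matrix and hypoxia lists were −0.06, −0.03 and −0.02. Without the A549 control, and so without A549, that of the fatty acid list was −0.01. Matrix remodelling and adhesion had 1 rise and 4 falls by both adjustments, over all genes and over the list alone (adjusted p = 0.559), with a median of −0.04 and a mean of 0.04 where the test leaned down. The protease inhibitor TIMP1 fell by 0.45 on the log2 scale (adjusted p = 0.00105). The collagenase MMP1 rose by 1.45 (adjusted p = 0.0088), with −0.84 in BEAS-2B. Its call was lost with siRNA 1 alone, with siRNA 2 alone and without H460 (adjusted p = 0.0777, 0.108 and 0.0908). MMP14 fell by 0.75 (adjusted p = 0.00367). Its level of 38.5 in the H460 controls compares with 40.3 that the H1299 share would bring, and without H460 its change was −0.29 (adjusted p = 0.150). Among the differentiation genes of alveoli and airways 1 of 13, the phosphate transporter SLC34A2, rose by both adjustments (median 0.06, adjusted p = 0.437). The cytosolic ribosomal proteins held 1 fall, RPLP1, by both adjustments (median −0.04, adjusted p = 0.437).

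In BEAS-2B, the normal line, TNFRSF10D, a decoy receptor for the death ligand TRAIL, fell from 2049 ± 83.4 to 972.5 ± 40.3 (log2 change −1.07, SE 0.104, adjusted p = 0.00167). The small GTPase RAB39B rose from 53 ± 5.66 to 141 ± 7.07 (1.40, SE 0.159, adjusted p = 0.0054), as it did in A549 (1.97) and H1299 (1.43). The cytokine LIF and the AP-1 subunit FOSL1 fell by 0.88 and 0.48 (adjusted p = 0.00229 and 0.041). Genes near the floor followed: CNTN1 went from 2.5 to 8.5, PPP2R2C, a phosphatase subunit, from 13.5 to 3, GLB1L2 from 1 and 1 to 0 and 0, and SPP1 was listed at 0 in both controls and at 2 and 6 after knockdown. MTRNR2L3, whose sequence resembles mitochondrial ribosomal RNA and may take its reads, went from 11.5 ± 3.54 to 67 ± 22.6 (adjusted p = 0.0335). The calls of GLB1L2, MTRNR2L3, PPP2R2C, SPP1 and RAB39B were lost in 12, 8, 2, 2 and 1 of the 15 fits that each left out 1 library.

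In BEAS-2B 31 genes changed (18 higher, 13 lower). By camera 4 lists were called, and 0 were called with an estimated correlation or by fry. The p53 targets fell with a median of −0.40 (1 lower, 8 lower adjusted over the list alone, adjusted p = 3.06e-07, adjusted p = 0.761 with an estimated correlation). Cholesterol synthesis, hypoxia and glycolysis, and NRF2 targets had medians of 0.24, 0.19 and 0.21 with 0 members called over all genes, and 0, 0 and 6 (5 higher, 1 lower) adjusted over the list alone (adjusted p = 0.00426, 0.0362 and 0.00426, adjusted p = 0.931, 0.931 and 0.690 with an estimated correlation). With siRNA 1 and siRNA 2 taken apart, the medians were −0.56 and −0.15 for p53 targets, −0.15 and 0.62 for cholesterol synthesis, −0.09 and 0.30 for hypoxia and glycolysis, and 0.24 and 0.29 for NRF2 targets, so the rises of cholesterol and hypoxia genes rest on the siRNA 2 library. The knockdown libraries differed from each other with a median absolute log2 deviation of 0.463, against 0.124 to 0.209 for the other pairs of libraries. The model uses the same spread for all groups, and the median SE was 0.154 in BEAS-2B, H1299 and H460 alike. The p-values in BEAS-2B may therefore be too small, and those in the cancer lines too large. The number of genes changed in BEAS-2B was 2963 without RNF20 siRNA 1, 1047 without siRNA 2, 10 and 11 without control siRNA 1 and 2, 8 to 14 without a library of another line except the A549 control, 3 without H460, and 1 with the replicate number as a block.

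In A549, interferon-stimulated genes, the antiviral genes switched on by interferon, rose: 18 of 24 were higher and 0 lower, and 22 were higher adjusted over the list alone (median log2 change 1.53, camera adjusted p = 1.88e-22, adjusted p = 0.0275 with an estimated correlation). The antiviral GTPase MX1 went from 123 to 1174 ± 134 (3.24, SE 0.386, adjusted p = 0.000767) and IFIT1 from 436 to 3118 ± 135 (2.83, SE 0.227, adjusted p = 0.000112). ISG15 and the RNA sensor DDX58 rose by 2.42 and 1.63 (adjusted p = 5.43e-05 and 0.00012). Among the largest falls, the interleukin 1 receptor accessory protein IL1RAP went from 2487 to 328.5 ± 14.8 (−2.92, SE 0.118, adjusted p = 5.21e-07), with −1.36 in H1299 and −2.10 in H460. The complement genes C4A and C4B, which carry identical values and cannot be told apart, went from 1347 to 115.5 ± 19.1 (−3.54, SE 0.478, adjusted p = 0.00163). RPS6KA2 was listed at 0 in the control and at 9 in each knockdown library, and C21orf56 at 0 in the control and at 4 and 9.

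In A549 1023 genes changed (565 higher, 458 lower), 363 by 2-fold or more. Of the 12 lists that camera called, the interferon list alone kept its call with an estimated correlation. G1/S genes (median 0.51, 12 higher, 16 adjusted over the list alone, adjusted p = 1.45e-10) and G2/M genes (0.41, 11 higher, 16 adjusted over the list alone, adjusted p = 3.71e-10) rose, with adjusted p = 0.0827 and 0.123 with an estimated correlation. NRF2 targets rose (0.54, 6 higher, 10 adjusted over the list alone, adjusted p = 4.19e-06, adjusted p = 0.0816 with an estimated correlation), and p53 targets fell (−0.42, 8 lower, 12 adjusted over the list alone, adjusted p = 3.44e-09, adjusted p = 0.193 with an estimated correlation). NF-kB and cytokine genes fell with 6 members lower (1 higher and 6 lower adjusted over the list alone, median −0.40, adjusted p = 0.000778, adjusted p = 0.220 with an estimated correlation), as did immediate early genes with 3 (4 adjusted over the list alone, −0.42, adjusted p = 0.000923, adjusted p = 0.123 with an estimated correlation). The other 5 were homologous recombination (1 higher, 5 adjusted over the list alone), epithelial (0) and alveolar genes (2, 3 adjusted over the list alone), all up, and histones (1 lower) and ribosomal proteins (0), both down, with adjusted p between 0.123 and 0.681 with an estimated correlation. Every A549 value rests on 1 control library. Fits without 1 library changed this, and the number of genes changed in A549 was 555 and 495 without RNF20 siRNA 1 and 2 of A549, 602 without H460, and 2384 without either knockdown library of BEAS-2B. With the replicate number as a block it was 3, and MX1, IFIT1, RPS6KA2, C21orf56, C4A and C4B lost their calls (adjusted p = 0.0528 to 0.127).

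In H1299, the matrix protein gene THBS1 rose from 963 ± 214 to 4652 ± 180 (log2 change 2.29, SE 0.147, adjusted p = 7.45e-06). IGFBP3, a carrier of insulin-like growth factors, rose from 99.5 ± 7.78 to 361.5 ± 21.9 (1.85, SE 0.134, adjusted p = 1.18e-05) and fell in A549 and H460 (−1.04 and −0.79, adjusted p = 0.00407 and 0.00205). Interferon-stimulated genes fell: 14 of 24 were lower and 0 higher, and 15 lower adjusted over the list alone (median −0.90, camera adjusted p = 2.46e-07, adjusted p = 0.327 with an estimated correlation). IFI44 went from 138 ± 1.41 to 12.5 ± 0.707 (−3.37, SE 0.257, adjusted p = 1.76e-05), SAMD9L from 170.5 ± 27.6 to 27 ± 5.66 (−2.62, adjusted p = 1.01e-05) and the apolipoprotein APOL1 from 109.5 ± 0.707 to 14 ± 1.41 (−2.88, SE 0.143, adjusted p = 1.60e-06). In A549, IFI44 and SAMD9L rose by 1.27 and 1.05 (adjusted p = 0.0352 and 0.0189). LBH went from 10.5 to 41.5 (adjusted p = 0.000153), and EHF was listed at 1 and 0 in the controls and at 5 and 4 after knockdown. In a contrast chosen after the values were seen, the interferon list differed between A549 and H1299 by a median of 2.42 (19 of 24 members higher in A549, camera adjusted p = 1.78e-30, adjusted p = 0.0110 with an estimated correlation).

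Sterol genes fell in H1299. Of 22 cholesterol synthesis genes 9 were lower, and 14 adjusted over the list alone (median −0.46, adjusted p = 1.89e-05, adjusted p = 0.678 with an estimated correlation), with the sterol sensor partner INSIG1 at −1.42 (adjusted p = 0.000225). Of 11 fatty acid synthesis genes 5 were lower, and 6 adjusted over the list alone (−0.53, adjusted p = 0.00143, adjusted p = 0.640 with an estimated correlation), with the desaturase FADS1 at −1.17 (adjusted p = 9.73e-05). Ribosome biogenesis genes rose with 13 higher and 14 adjusted over the list alone (0.49, adjusted p = 3.90e-07, adjusted p = 0.327 with an estimated correlation), and NCL went from 14362 ± 167 to 24448 ± 364. The other called lists were G1/S genes (0.24, 7 higher, adjusted p = 0.0196) and ribosomal proteins (0.16, 3 higher, adjusted p = 0.0348), both up, and p53 targets (−0.32, 2 higher and 9 lower, adjusted p = 0.0242) and apoptosis regulators (−0.30, 6 lower, adjusted p = 0.0366), both down. Adjusted over the list alone these were 9 higher and 1 lower, 1 higher, 2 higher and 11 lower, and 10 lower, with adjusted p = 0.640, 0.716, 0.678 and 0.327 with an estimated correlation. The 2 p53 targets that rose, chosen after their values were seen, were AEN (0.91) and BAX (0.36). The collagenase MMP1 rose by 3.94 and CLDN1 by 1.51 (adjusted p = 0.00166 and 2.07e-05). In H1299 3024 genes changed (1456 higher, 1568 lower), 430 by 2-fold or more. The number of genes changed in H1299 was 1273 and 1829 without control siRNA 1 and 2, 1365 and 1300 without RNF20 siRNA 1 and 2, 4986 and 4987 without BEAS-2B RNF20 siRNA 1 and 2, and 4920 without BEAS-2B.

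In H460, cell cycle genes rose. Of 24 G1/S genes 19 were higher, and 21 adjusted over the list alone (median 0.69, camera adjusted p = 1.21e-13, adjusted p = 0.123 with an estimated correlation), led by E2F2 (log2 change 1.75, SE 0.160, adjusted p = 6.02e-05). Of 24 G2/M genes 19 were higher, and 21 adjusted over the list alone (0.60, adjusted p = 2.05e-12, adjusted p = 0.162 with an estimated correlation), and of 19 homologous recombination genes 10 were higher, and 12 adjusted over the list alone (0.36, adjusted p = 1.39e-05, adjusted p = 0.162 with an estimated correlation). Ribosome biogenesis genes rose with 9 higher (12 adjusted over the list alone, 0.35, adjusted p = 2.76e-06, adjusted p = 0.217 with an estimated correlation). Targets of p53 fell with 11 lower (1 higher and 12 lower adjusted over the list alone, −0.51, adjusted p = 6.58e-06), and TGF-beta and YAP targets with 6 (1 higher and 9 lower adjusted over the list alone, −0.45, adjusted p = 0.000202). Immediate early genes fell with 9 lower (10 adjusted over the list alone, −0.47, adjusted p = 0.000976) and HOX genes with 5 (6 adjusted over the list alone, −0.18, adjusted p = 0.0346). With an estimated correlation the adjusted p of these 4 lists were 0.257, 0.252, 0.175 and 0.201. The other 5 called lists were NRF2 targets (3 higher) and cholesterol synthesis (4), both up, and histones (3 lower), mesenchymal genes (5) and interferon-stimulated genes (3 higher, 7 lower), all down. Adjusted over the list alone these were 4 higher and 1 lower, 4 higher, 4 lower, 6 lower, and 3 higher and 9 lower, with adjusted p between 0.257 and 0.730 with an estimated correlation. With the H1299 share (described below) subtracted from the controls, an alternative chosen after seeing the data, the HOX and NRF2 calls were lost (medians −0.10 and 0.19, adjusted p = 0.452 and 0.103) and ribosomal proteins were called lower (−0.12, adjusted p = 0.0480). MOB3B rose from 24.5 ± 9.19 to 83 ± 22.6 (1.74, adjusted p = 0.000822), and the near-identical pair ANXA8 and ANXA8L1 was listed at 0 in both controls and at 3 in each knockdown library. Each of these 2 lost its call in 4 of the 15 fits that left out 1 library.

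Among genes above the lowest quartile of level, the largest falls in H460 were those of the cancer-testis genes GAGE2D, GAGE8, GAGE2E and GAGE2C, near-identical copies that cannot be told apart (log2 changes −6.39, −6.38, −6.37 and −6.35, adjusted p = 0.000376, 0.000895, 0.000898 and 0.000663). These genes are abundant in H1299, and between 91.6% and 92.2% of their level in the H460 controls would come from the H1299 share there. With that share subtracted their log2 changes were −2.58, −2.26, −2.28 and −2.69, and none passed (adjusted p = 0.0629, 0.179, 0.168 and 0.0645). The share was measured on 31 genes at 500 or more in every H1299 library and at 5 or fewer in BEAS-2B and A549 knockdown libraries. Their median level was 2.64% of that in H1299 in H460 control siRNA 1, 0.859% in control siRNA 2, and 0.0106% and 0.0399% in the knockdown libraries. Several of these genes are GAGE copies or pairs listed with identical values, such as CTAG1A and CTAG1B, so they are fewer than 31 separate measures. The quartiles of the share were 1.92% and 2.81% in control siRNA 1 and 0.641% and 1.05% in control siRNA 2. A share with the copies merged was not computed. In H460 2907 genes changed (1202 higher, 1705 lower), 552 by 2-fold or more (183 higher, 369 lower). For 145 of the 1705 falls (8.50%), 129 of the 369 falls of 2-fold or more (35.0%) and 49 of the 50 largest, 50% or more of the loss would come from the H1299 share. The number of genes changed in H460 was 1695 and 1643 without control siRNA 1 and 2, 1269 and 1505 without RNF20 siRNA 1 and 2, 4864 and 4857 without BEAS-2B RNF20 siRNA 1 and 2, and 4735 without BEAS-2B.

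**Figure D4:**
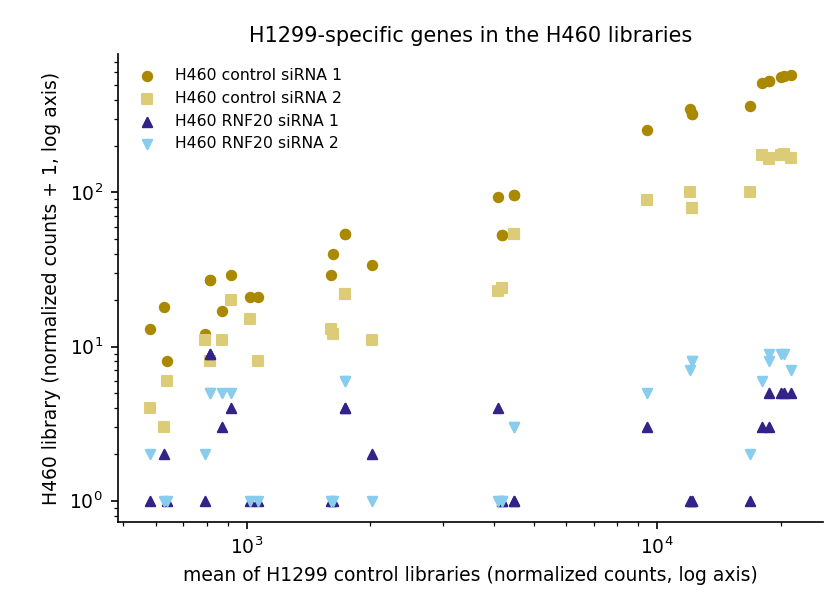
Level of 31 genes specific to H1299 in each H460 library (normalized read counts plus 1, log axis) against their mean level in the H1299 control libraries (log axis), with 1 point per gene and library. All 31 genes lie higher in H460 control siRNA 1 than in control siRNA 2, with a median ratio of 3.19, and the median share in the knockdown libraries is 0.0106% and 0.0399%.

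Averaged over the 3 cancer lines, 4661 genes changed (2204 higher, 2457 lower), and 104 were called higher and 213 lower in each of A549, H1299 and H460. G1/S genes rose with 20 of 24 higher (median 0.47, 20 higher and 1 lower adjusted over the list alone, camera adjusted p = 2.72e-10), G2/M genes with 18 higher (0.37, 20 higher and 1 lower adjusted over the list alone, adjusted p = 7.51e-09) and ribosome biogenesis with 12 higher (0.29, 15 adjusted over the list alone, adjusted p = 5.00e-06), each with adjusted p = 0.243 with an estimated correlation. Targets of p53 fell with 12 lower (−0.45, 13 adjusted over the list alone, adjusted p = 2.60e-06, adjusted p = 0.282 with an estimated correlation) and histones with 7 (−0.59, 9 adjusted over the list alone, adjusted p = 0.00136, adjusted p = 0.322 with an estimated correlation). Homologous recombination genes and NRF2 targets were also called up, and NF-kB and immediate early genes down (camera adjusted p = 0.00133, 0.0019, 0.0322 and 0.0481). With an estimated correlation these were 0.243, 0.243, 0.404 and 0.282. In H460 the NF-kB list was not called (median −0.25, camera adjusted p = 0.223). Several of the lists called over the cancer lines were not called in H1299. Its G2/M genes had a median of 0.06 (3 higher, 1 lower, camera adjusted p = 0.200) and its homologous recombination genes −0.11. Its NRF2 targets had 0.03 (0 higher, 1 lower) and its immediate early genes 0.15 (6 higher, 1 lower). Histones and NF-kB genes had medians of −0.43 and −0.39 there (camera adjusted p = 0.0523 and 0.0918). In A549 the ribosome biogenesis genes had a median of 0.06 (adjusted p = 0.514), and limma called 0 of them by either adjustment. This made 9 of 23 lists, of which camera called 0 with an estimated correlation and fry called all 9. Pairs of cancer lines, which share no library, overlapped beyond independent lists. Independence is not a full yardstick, since the model gives each gene 1 spread for all lines, which favours calling the same genes. That alone would favour the same and opposite directions alike. The H460 controls also held an H1299 share, so H1299 and H460 are not fully separate. A549 and H1299 shared 154 higher and 267 lower genes (55.4 and 48.4 for independent lists), A549 and H460 196 and 310 (45.8 and 52.6), and H1299 and H460 503 and 643 (118 and 180). In these pairs 66, 28 and 61 genes were called in opposite directions. Of the 13 genes lower in BEAS-2B, RNF20 included, 7 were lower in A549, 6 in H1299 and 8 in H460 (0.401, 1.37 and 1.49 for independent lists). Of the 18 higher there, 2, 3 and 0 were higher in these lines (0.685, 1.77 and 1.46 for independent lists). Across all tested genes, which are not independent replicates, Pearson's r of the log2 changes was 0.20, 0.219 and 0.25 for these pairs of cancer lines and 0.0839, 0.00574 and 0.0323 for BEAS-2B with A549, H1299 and H460, 6 correlations in all. Without H460 the number of genes changed on average over 3 cancer lines was 2274.

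Changes differed between the cancer lines and BEAS-2B for 1373 genes (590 with a higher and 783 with a lower change in the cancer lines). The SEs assume the same spread in every group, although the BEAS-2B knockdown libraries differed more than any other pair. The p-values of this difference may thus be too small. BMF, which promotes cell death, went from 384 to 134 ± 14.1 in A549, from 1020 ± 65.8 to 267 ± 14.1 in H1299 and from 1272 ± 6.36 to 368.5 ± 7.78 in H460. In BEAS-2B it stood at 139 ± 12.7 and 234 ± 93.3 (difference −2.43, SE 0.247, adjusted p = 0.000355). PPP2R2C had a difference of 2.33 (SE 0.269, adjusted p = 0.000854), and SERPINB2, an inhibitor of plasminogen activators, 2.17 (SE 0.391, adjusted p = 0.0083), with 166 ± 8.49 and 45.5 ± 3.54 in BEAS-2B. MTRNR2L3 had a difference of −2.57 (adjusted p = 0.00637). RTN1 (2.20, adjusted p = 0.0266), the keratin KRT85 (1.93, adjusted p = 0.0304) and the fibrinogen chain FGG (−2.65, adjusted p = 0.0322) lost their calls in 9, 8 and 11 of the 15 fits that each left out 1 library, and SERPINB2 in 1. LIN28B, a regulator of let-7 RNAs (−2.82, SE 0.792, adjusted p = 0.0484), lost its call in 10 of these, and its loss of 70 in H460 compares with 103 that the H1299 share would account for (−1.72, adjusted p = 0.0520, without H460).

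Between these groups of lines the change of G1/S genes was higher in the cancer lines (median difference 0.50, 14 members higher, 18 adjusted over the list alone, adjusted p = 9.07e-10), as was that of G2/M genes (0.38, 10 higher, 19 adjusted over the list alone, adjusted p = 9.07e-10) and of ribosome biogenesis genes (0.32, 5 higher, 6 adjusted over the list alone, adjusted p = 5.83e-05). The change was lower for cholesterol synthesis (−0.38, 3 lower, adjusted p = 0.00331) and histones (−0.49, 2 lower, adjusted p = 0.0330), with the same counts adjusted over the list alone. The cancer lines were not alike in all of these lists: cholesterol synthesis had medians of −0.05 in A549, −0.46 in H1299 and 0.20 in H460, against 0.24 in BEAS-2B. Ribosome biogenesis had 0.06, 0.49 and 0.35, against −0.01, and G2/M genes had 0.41, 0.06 and 0.60, against −0.09. In BEAS-2B the 2 siRNAs moved the cholesterol and histone lists in opposite directions, with medians of −0.15 and 0.62 for cholesterol synthesis and −0.50 and 0.50 for histones. With an estimated correlation the adjusted p of these 5 lists were 0.265, 0.265, 0.652, 0.792 and 0.785. In 5 lists that were not called, the signs of median, mean and test differed: matrix remodelling (median −0.36, mean 0.08, test down), epithelial genes (−0.06, −0.04, up), HOX genes (0.06, −0.03, down), apoptosis regulators (0.01, −0.13, down) and ribosomal proteins (0.02, −0.01, down). BEAS-2B is the only normal line. The number of genes whose change differs between cancer lines and BEAS-2B was 4437 and 2387 without its RNF20 siRNA 1 and 2, 504 and 325 without its control siRNA 1 and 2, 409 without H460, and 39 with the replicate number as a block. Of the genes named for this difference BMF alone kept its call with that block. Without 1 library of H1299 (control siRNA 1, RNF20 siRNA 1 or 2) or 1 knockdown library of H460 it lay between 775 and 867.

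The 2 RNF20 siRNAs were compared across genes in BEAS-2B, H1299 and H460, with each set against its own control library so that no library was shared. RNF20 was the 1 gene called for each siRNA and for both. Pearson's r of the average changes was 0.449 across genes, which are not independent replicates, and 0.00272 in simulated data with no effect. With pooled controls r was 0.646 against a simulated 0.338, and the covariance 0.0792 against 0.0246. The simulated noise was independent between genes and libraries, so the simulated r follows from whether controls are shared. It does not cover structure that real libraries may have in common. Within a line r with split controls was 0.559 in H1299, 0.652 in H460 and −0.211 in BEAS-2B, where the siRNAs did not move genes alike. Without BEAS-2B r was 0.685.

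**Figure D5:**
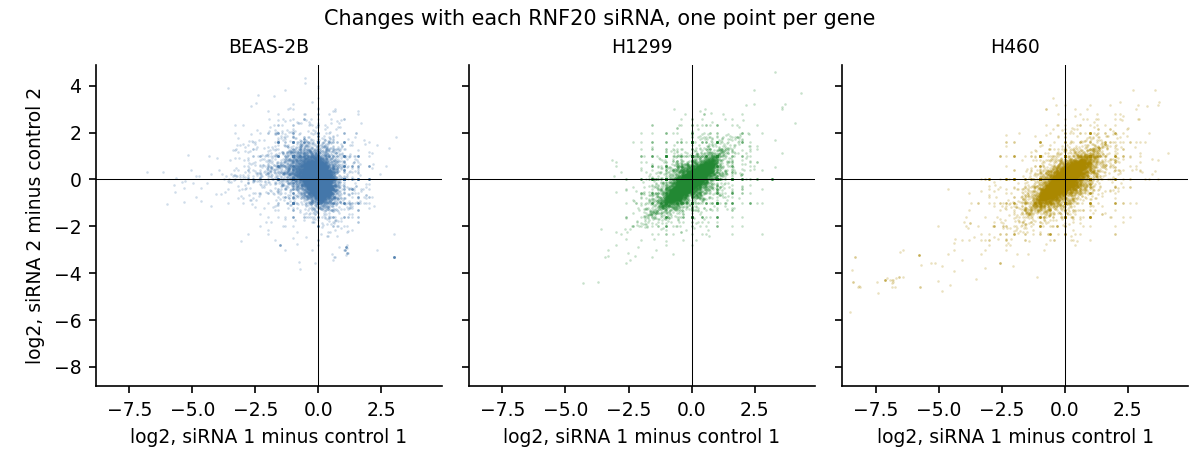
Log2 change of each tested gene with RNF20 siRNA 1 against control siRNA 1 (x axis) and with RNF20 siRNA 2 against control siRNA 2 (y axis) in BEAS-2B, H1299 and H460, with 1 point per gene. The points follow the diagonal in H1299 (r = 0.559) and H460 (r = 0.652) and not in BEAS-2B (r = −0.211).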

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

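Tests of H1299 transcripts in the H460 controls, of the strength of the BEAS-2B knockdown, of the list calls under subtraction and trend removal, and of the contrast between A549 and H1299, as well as the counts of other splits, were chosen only after the result was seen, whereas the tests of length and GC content and of siRNA sequence on the BEAS-2B libraries were set down before.

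The change after knockdown differed between the cancer lines and BEAS-2B, by a test of the difference itself, for 1373 genes, against which 4 of 100 splits within lines (drawn from 648) gave as many, the real one included. The highest other split gave 3435, more than the real count, and differed from the real one only in BEAS-2B, where control siRNA 1 stood with RNF20 siRNA 2. Because the splits also regroup the cancer libraries, their share reflects any effect of knockdown in those lines. It cannot decide whether the difference from BEAS-2B is due to chance. The other splits that gave as many all regrouped the BEAS-2B libraries, so their labels do not set the real count apart, and these counts point to a structure of the BEAS-2B libraries. With the replicate block 39 genes whose change differs between cancer lines and BEAS-2B were left. The gene lists that differed were G1/S genes (median difference 0.50), G2/M genes (0.38), ribosome biogenesis (0.32), cholesterol synthesis (−0.38) and histones (−0.49). With an estimated correlation camera called 0 of these (adjusted p between 0.265 and 0.792). In BEAS-2B the 2 siRNAs moved the cholesterol and histone lists in opposite directions. Among called genes above the lowest quartile of level, those with the largest differences were PPP2R2C (2.33), RTN1 (2.20), SERPINB2 (2.17), KRT85 (1.93), LIN28B (−2.82), FGG (−2.65), MTRNR2L3 (−2.57) and BMF (−2.43). RTN1, KRT85, FGG, LIN28B and SERPINB2 lost their calls in 9, 8, 11, 10 and 1 of the 15 fits without 1 library. LIN28B log2 change difference between cancer lines and BEAS-2B was −1.72 without H460 (adjusted p = 0.0520) and −0.88 with the H1299 share subtracted (adjusted p = 0.402), a share larger than its whole level in the H460 controls.

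The BEAS-2B knockdown libraries differed from each other with a median absolute log2 deviation of 0.463 over genes, against 0.171 for the BEAS-2B control libraries. With length and GC trends removed, their spread was still 2.54 times that of the widest other pair. Effects of the siRNA sequences that all lines share are argued against by an r across genes of −0.0518 between the siRNA 1 minus siRNA 2 difference in BEAS-2B and in the mean of the other lines. Weaker knockdown, with 14.2% of RNF20 left, stays open: the changes with the 2 siRNAs had an r of −0.211 or 0.0522, depending on which control library was set against which siRNA. A difference between normal and cancer cells cannot alone set these libraries apart, since both are BEAS-2B with RNF20 siRNA. A change in 1 of the 2 cultures or an interaction of an siRNA with this line stays open. The design holds 1 normal line and 1 library per siRNA, so neither was tested.

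H1299-specific transcripts stood in the H460 control libraries at a nearly common share of their H1299 level. In the library with the poorer match, 90.3% of 31 genes lay within 2-fold of the median share. H1299 RNA or reads in these libraries would give such a common share. Several of the 31 are near-identical copies or pairs with identical values, so the genes are not 31 separate measures. Loss of RNF20 as the cause is argued against by the control libraries themselves, which differed by a median of 1.63 on the log2 scale over these genes, against a median absolute deviation of 0.180 over all genes. Carry-over at 1 level across the run is argued against by the H460 knockdown libraries, with median shares of 0.0106% and 0.0399% over the same genes, against 0.859% in the lower control library. For the 31 genes the BEAS-2B and A549 libraries do not bear on this, since these genes were chosen to be low there. A set of 25 H1299-specific genes chosen without regard to BEAS-2B had a median share of 0% in each BEAS-2B library. A set of 27 chosen without regard to A549 had 0% in the A549 control and 0.0106% and 0% with RNF20 siRNA 1 and 2. These shares also argue against carry-over at 1 level across the run. Whether the H1299 material entered as cells, RNA or misassigned reads stays open, and no biological explanation was tested.

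The interferon-stimulated genes moved apart between A549 and H1299, with a median difference of 2.42 by a test of the difference chosen after the values were seen. All A549 values rest on 1 control library.

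The 10 list calls in the mean over 4 lines stood in the same direction with length and GC trends removed (10 of 10) and with the H1299 share subtracted (10 of 10), so neither is the whole cause. In 27 of 100 splits within lines as many lists were called, the real one included, and the highest other split called 15 against the real 10, so chance cannot be excluded for the number of list calls. For the number of genes, 2 of 100 splits gave as many as the real 4005 (highest other 4159, with the same BEAS-2B regrouping), and over the cancer lines 1 of 100 (4661, highest other 3121). These shares argue against an arbitrary grouping of these libraries for both counts. For the mean over 4 lines the BEAS-2B labels do not set the real count apart. Chance differences between cultures are not covered, since nothing ties the libraries to separate cultures.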

How the results depend on the processing

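The alternatives without H460, without BEAS-2B, with the H1299 share subtracted, with length and GC trends removed, with crossed numbers, and those of the siRNA agreement with another pseudocount, filter or without BEAS-2B were chosen after seeing the data.

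Of 165 gene and list results, 165 kept direction and side of the threshold with each of the 2 other scalings, 163 with pseudocount 0.25, 154 without a filter, 163 of 164 with the strict filter, 126 with the replicate block, 148 and 153 with siRNA 1 and siRNA 2 alone, 156 with the H1299 share subtracted, 161 of 162 with trends removed, 145 of 149 without BEAS-2B and 115 of 157 without H460. siRNA identity as a random block kept 141 of 142 gene results, and camera could not take this block. Where a cause is not named, the cause was not tested. Fits that leave a group with 1 library assume that it varies like the others. No A549 value could be had without its control, so the means are then those of the other lines. Calls of genes named in the text that were lost without H460, beside those given in the report, were ALDH3A1, ESRP1, ITGAV, SC5DL, INSIG1, ELOVL5 and RPLP1 in the mean over 4 lines (adjusted p = 0.0520 to 0.165), MTRNR2L3, SPP1, CNTN1, RAB39B, PPP2R2C and GLB1L2 in BEAS-2B (0.0530 to 0.227), and RTN1, SERPINB2, FGG and MTRNR2L3 in the difference (0.0505 to 0.128).

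Leaving out 1 library at a time gave 8 to 2963 genes changed in BEAS-2B, 495 to 2384 genes changed in A549, 1273 to 4987 genes changed in H1299 and 1269 to 4864 genes changed in H460. It gave 3110 to 5984 genes changed on average over 4 lines, 3639 to 6481 genes changed on average over 3 cancer lines and 325 to 4437 genes whose change differs between cancer lines and BEAS-2B. RNF20 stayed between −3.59 and −3.44, and 10 to 13 lists were called. In the order BEAS-2B, A549, mean over 4 lines, cancer lines and difference, the counts without H460, which leaves fewer libraries, were 3, 602, 1712, 2274 and 409. Without BEAS-2B they were 2320 (A549), 4920 (H1299), 4735 (H460) and 6470 (mean). With siRNA 1 alone they were 231 (BEAS-2B), 674 (A549) and 802 (difference), and with siRNA 2 alone 1280 (BEAS-2B) and 3194 (difference). BEAS-2B gave 48 genes with pseudocount 0.25, 12 without a filter, 68 with trends removed, and 0 in limma when fitted alone, where 825 had an unadjusted p under 0.05. With an estimated correlation camera called 0 lists, 5 having an unadjusted p under 0.05, and fry called 14. The agreement of the 2 RNF20 siRNAs, as r, was 0.533 with crossed controls, 0.646 with pooled controls, 0.337 with pseudocount 0.25, 0.356 without a filter, 0.525 with the strict filter and 0.685 without BEAS-2B.

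Same-numbered libraries did not deviate alike (r of same-numbered deviations −0.31, 0.01 and −0.01 in BEAS-2B, H1299 and H460). The negative r in BEAS-2B means that control siRNA 1 deviated more like RNF20 siRNA 2, a crossed pattern. There the replicate 1 minus replicate 2 difference had a Spearman correlation with GC content of 0.237 in controls and −0.225 in knockdowns. What crossed these libraries was not tested. With the replicate block, which costs degrees of freedom, there were 1 (genes changed in BEAS-2B), 3 (genes changed in A549), 1160 (genes changed in H1299), 1267 (genes changed in H460), 1971 (genes changed on average over 4 lines), 2486 (genes changed on average over 3 cancer lines) and 39 (genes whose change differs between cancer lines and BEAS-2B). Of the 165 gene and list results 38 lost their calls: MTRNR2L3, SPP1, CNTN1, RAB39B, PPP2R2C, TNFRSF10D and GLB1L2 in BEAS-2B (adjusted p = 0.0789 to 0.518), MX1, IFIT1, RPS6KA2, C21orf56, C4A and C4B in A549 (0.0528 to 0.127), ANXA8 and ANXA8L1 in H460, all named differences except BMF (0.0559 to 0.159), and 16 genes in the mean over 4 lines (0.0502 to 0.127). These 16 were ALDH3A1, HIST1H2BD, HIST1H2BC, HIST1H3H, ACTA2, KRT7, KRT18, ESRP1, MMP1, ITGAV, IFI44, SC5DL, INSIG1, FADS1, HOXB3 and RPLP1. With the numbers crossed in BEAS-2B the counts were 413 (BEAS-2B), 1722 (A549) and 2573 (difference).

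Directions turned for these mean values. The Matrix remodelling and adhesion list on average over 4 lines was −0.0618 with siRNA 1 alone and ran from −0.0332 to 0.106 over the fits without 1 library. The Fatty acid synthesis list on average over 4 lines was −0.0445 with siRNA 1 alone, −0.0674 without H460 and −0.0454 without BEAS-2B, and ran from −0.0599 to 0.105. The Hypoxia and glycolysis list on average over 4 lines was −0.0349 with siRNA 1 alone and ran from −0.0193 to 0.123. The Cholesterol synthesis list on average over 4 lines was 0.0566 with siRNA 2 alone and ran from −0.13 to 0.062. The Interferon-stimulated genes list on average over 4 lines ran from −0.371, without the A549 control and so without A549, to 0.168. The Immediate early genes list on average over 4 lines was 0.033 without H460, and the Cytosolic ribosomal proteins list on average over 4 lines 0.00763 with siRNA 2 alone. Without the A549 control, and so without A549 in the mean, 3 genes turned: DDX58 log2 change on average over 4 lines ran from −0.063 to 0.391, ISG15 log2 change on average over 4 lines from −0.279 to 0.442 and KLF6 log2 change on average over 4 lines from −0.293 to 0.0564. With the H1299 share subtracted HMGA2 was 0.33 and MMP14 0.22, but that share exceeds their mean level in the H460 controls (120% and 105%), so that these signs come from controls set to the floor or near it and show no turn. Without H460 the values were −0.90 and −0.29.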

Other observations

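The marker lists in this part were fixed before the data were examined, and no test in it was chosen after the result was seen.

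Of the basal epithelial markers 8 were tested and 1, the neurotrophin receptor NGFR, rose on average over the 4 lines (log2 change 0.67, SE 0.227, adjusted p = 0.0497). Their median level was 736 in BEAS-2B controls, where the keratin KRT17 reached 10677, and 6.5, 1.5 and 9.75 in A549, H1299 and H460 controls. Of 3 neuroendocrine markers tested, the vesicle protein SYP rose (0.73, SE 0.226, adjusted p = 0.0326). Of 7 fibroblast markers POSTN fell (−0.87, SE 0.297, adjusted p = 0.0499). The fibroblast marker LUM was the highest of its list in the A549 control (327) and in the H460 controls (970). Of 4 immune markers and 1 endothelial marker tested, limma called 0. CD68 was the highest immune marker in every group, at 194 to 1881.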
